A study of Mus musculus with 6 samples.

How the data were processed

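RNA-seq libraries came from mouse 2-cell embryos that had developed in KSOM after microinjection of zygotes with Suv39h1wt or Suv39h1mut mRNA, or without injection; the strain is not given in the labels. Per the submitters' processing notes, 2 ng of total RNA was amplified with random and poly-T primers, base calls were made with CASAVA 1.8.2, reads were aligned to mm9 with TopHat2 2.0.14 and Bowtie, and gene counts were made with HTSeq 0.6.1. The annotation release, the strand setting and the way reads were assigned to repeat families are not stated there, so values of antisense, overlapping and multi-copy genes are uncertain. Libraries were grouped as 3 groups of 2 from the labels, and 0 columns of per-sample values were left unmapped.

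Per the file headers, the deposited gene table holds raw read counts for 26982 genes in 6 libraries, and the deposited repeat table holds raw counts for 1183 families in the 4 injected libraries only. The normalized counts deposited by the authors equalled the raw count divided by 1 size factor per library when tested on the files. The signal values, the normalized counts in the deposited files, were made by the authors by that division. They were used for their size factors, for gene length and for the spread within groups of the genes the authors list as differentially expressed. The deposited log2 fold changes and p-values are the authors' own, for Suv39h1wt vs Suv39h1mut; their test is not stated. The log2 values and the adjusted p-values in the authors' deposited table were used as a description beside the tests made here. The values divided by gene length were used only to obtain gene length. Repeat families were not compared with non-injected embryos, since the repeat table has no columns for them.

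All tests started from the raw counts, with R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package, version 1.17.8. The main fit was edgeR's robust quasi-likelihood F test on all 6 libraries with group as the only factor, TMM scaling and filterByExpr with a minimum count of 10, which left 17638 genes and 3 residual degrees of freedom. The repeat table was fitted alone in the same way, with library sizes from that table, 1082 families and 2 residual degrees of freedom. Benjamini-Hochberg adjusted p under 0.05 counted as passing. Comparisons were Suv39h1wt vs Suv39h1mut, Suv39h1wt vs non-injected and Suv39h1mut vs non-injected. The biological coefficient of variation was 0.862 for genes and 0.574 for repeat families, so with 2 libraries per group only large changes of single genes could pass. Log2 fold changes and SE are from the edgeR fit. Where a whole group had 0 counts, a bound against a floor of 3 counts per library is given in place of a fold. It is the mean CPM of the other group over the mean CPM of that floor, so it is a ratio of group means and not a bound for each library.

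The design, the 19 gene lists and the alternatives were fixed before the data were examined. Lists were tested with limma's camera on log2 CPM at a preset correlation of 0.01, adjusted over 57 tests, with an estimated correlation and fry as checks; median and mean log2 fold changes and the numbers of higher and lower members are given beside each test. Repeat classes, assigned here from patterns in the family names, were tested alike in 11 classes. The genes named are, for each comparison, Suv39h1, then those past the threshold with non-overlapping libraries and at least 1 CPM, or, where none passed, the 5 with the smallest p in each direction, and per list the 2 members with the smallest p. Of the list members so picked, those of lists that passed and of the H3K9, interferon, pluripotency and other-cell lists are printed where space allowed; some of the genes picked are not reported here. Ubb, Men1 and Flad1 were chosen from the authors' deposited table after their values were seen.

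Libraries of all groups carry the numbers 1 and 2, and the labels do not say what a number marks. Deviations of same-numbered libraries from their group means had correlations of 0.167, 0.141 and 0.196 over all genes between the 3 pairs of groups, and 0.479 to 0.532 over 6357 genes above 10 CPM. All 3 were over 0.1, so the number was treated as a pairing and a fit with it as a block was made beside the main fit. Genes are not independent, so such correlations do not show that the numbers mark true pairs. The block lowered the coefficient of variation from 0.862 to 0.774.

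The fits were tested on simulated data with the means and spread of these libraries, with 200 genes changed per set. Recovery was counted only over the changed genes that passed the low-count filter. In Suv39h1wt vs Suv39h1mut these were 65, 61 and 62 genes with 4-fold, 16-fold and 64-fold changes. Of these edgeR recovered 4.62%, 50.8% and 66.1%, and DESeq2 20.0%, 62.3% and 88.7%. Comparisons with shared controls were set beside 20 simulated sets of unchanged groups. GC content and words of 31 bases shared between genes were taken from GENCODE M21 transcripts, matched by gene identifier. Gene length came from the authors' values, as the normalized count over the value divided by gene length. Coordinates are those of the mm9 table.

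Alternatives were DESeq2 size factors, upper-quartile scaling, DESeq2's Wald test, no filter, at least 10 counts in every library, only the 4 libraries compared, the replicate block, an added fold-change threshold, adjusted p under 0.1, Suv39h1 removed before scaling, scaling of repeats from the gene table, and each library left out in turn. A group left with 1 library was assumed to vary like the others. The low-count filter was applied anew in each fit with a library left out, so the genes and repeat families tested, and the members of a list, can differ from the main fit. Chosen after seeing the data were DESeq2 with a fold-change prior, removal of mitochondrial rRNA, Lars2 and mir-689 genes or of structural RNA and simple repeats before scaling, the authors' size factors for repeats, the block with an estimated correlation, the block and left-out libraries for repeat classes, the block with each library left out for list tests, other scalings for list tests, simulated unchanged groups with the difference between library numbers or with 1 library left out, and left-out libraries for the chromosome 12 window. Annotation terms with 15 to 500 tested genes were also tested after the data were seen.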

Results

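RNA was sequenced from mouse embryos at the 2-cell stage, the stage at which the embryonic genome is broadly switched on and stored maternal transcripts are being cleared. Zygotes had been microinjected, 18 h after hCG (the hormone that triggers ovulation), with 0.6 µg/µl of mRNA for a wild-type form (Suv39h1wt) or a mutant form (Suv39h1mut) of Suv39h1, or had not been injected. SUV39H1 is a histone methyltransferase that deposits trimethylation of lysine 9 of histone H3 (H3K9me3), a mark of constitutive heterochromatin; the labels do not say what the mutation is. There were 2 libraries in each of the 3 groups, 6 in all. Total counts over genes were 33.5 M and 36.4 M in the non-injected libraries, 48.6 M and 46.7 M in the Suv39h1mut libraries, and 46.0 M and 43.1 M in the Suv39h1wt libraries. Between 18463 and 22349 of the 26982 genes had at least 1 count in a library. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 took 41.9% ± 6.94 of gene counts in non-injected, 33.1% ± 6.16 in Suv39h1mut and 37.0% ± 14.5 in Suv39h1wt embryos (SD, n = 2). A second table held counts for 1183 repeat element families in the 4 injected libraries, with 23.3 M to 28.6 M counts each. Gene levels are given as CPM (counts scaled to library size) after TMM scaling, as mean ± SD over the 2 libraries of a group, and fold changes as log2 values ± SE. The labels do not say that the 2 libraries of a group came from separate collections of embryos, so p-values measure only the spread between these libraries.

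Suv39h1 itself (ENSMUSG00000039231, mm9 chromosome X, 7638297 to 7651886) was read at similar levels in all 3 groups. Its level was 44.6 ± 9.33 CPM in Suv39h1wt, 34.8 ± 9.60 CPM in Suv39h1mut and 38.2 ± 4.42 CPM in non-injected embryos, from 1144 to 2669 counts per library. The log2 fold change was 0.36 ± 0.51 for Suv39h1wt vs Suv39h1mut, 0.23 ± 0.51 for Suv39h1wt vs non-injected and -0.13 ± 0.51 for Suv39h1mut vs non-injected, with adjusted p of 1, 0.951 and 0.984 in edgeR's quasi-likelihood test. The Suv39h1mut vs non-injected value was 0.13 without Suv39h1mut replicate 1 and 0.04 without non-injected replicate 1. No excess of Suv39h1 reads beyond the spread was thus detected in injected embryos, so these counts do not show the injected mRNA, and protein was not measured.

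**Figure D1:**
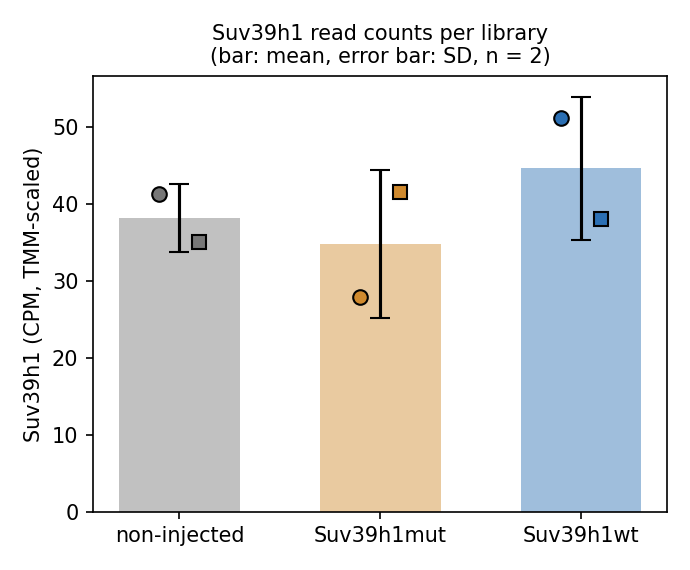
Suv39h1 level in CPM (vertical axis, TMM-scaled) in the 3 groups. Bars are means, error bars SD over 2 libraries, circles library number 1 and squares number 2; the group means of 38.2, 34.8 and 44.6 CPM differ by less than the error bars span.

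The comparison of Suv39h1wt with Suv39h1mut embryos sets 2 injected groups side by side. Among the 5 genes with the smallest p in each direction, Igf2bp1 and Rffl stood at appreciable levels in all libraries. Igf2bp1, an RNA-binding protein of the IGF2 mRNA-binding family (chromosome 11, 95818477 to 95867254), was at 70.0 ± 10.9 CPM in Suv39h1wt and 19.9 ± 5.41 CPM in Suv39h1mut embryos, a log2 fold change of 1.82 ± 0.52. Rffl, a RING-finger ubiquitin ligase (chromosome 11, 82615951 to 82684712), was at 2.99 ± 0.72 CPM against 20.7 ± 4.63 CPM, a log2 fold change of -2.80 ± 0.73. Dhx34, an RNA helicase that acts in nonsense-mediated decay, had 133 and 265 counts in the Suv39h1wt libraries and 7 and 1 in the Suv39h1mut libraries. Rbfa, a ribosome-binding factor that acts in assembly of the mitochondrial ribosome, had 377 and 999 counts against 12 and 61. Csf2rb, the shared beta chain of the receptors for interleukin 3, interleukin 5 and GM-CSF, had 28 and 717 counts against 2 and 3, and 6030468B19Rik had 5 and 982 against 2 and 4. Without Suv39h1wt replicate 2 the log2 fold change fell from 7.69 to 3.34 for Csf2rb and from 7.86 to 0.63 for 6030468B19Rik. On the lower side, Cdhr1, a cadherin of photoreceptors, had 0 counts in both Suv39h1wt libraries against 71 and 453. It was at least 74.0-fold lower as a ratio of group means, against a floor of 3 counts per library. The ferritin pseudogene Fth-ps2 had 4 and 0 counts against 233 and 355. Gm16282, annotated as antisense, was at least 46.6-fold lower and the pseudogene Gm10988 at least 35.3-fold lower, both with 0 counts in the Suv39h1wt libraries; reads of pseudogenes and antisense genes can belong to their parent or partner genes.

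None of these genes passed the main test: edgeR's quasi-likelihood test called 0 of 17638 genes for Suv39h1wt vs Suv39h1mut at an adjusted p of 0.05, with a smallest adjusted p of 1. Each of the genes named but Igf2bp1 passed under at least 1 of the alternative settings. At an unadjusted p under 0.05 it counted 480 genes, 223 higher and 257 lower in Suv39h1wt, where chance alone gives 881.9; with the replicate number as a block it called 0 and counted 396 higher and 313 lower. DESeq2's Wald test called 44 genes, 27 higher and 17 lower, of which 9 had a group at 0. In data simulated with the spread that edgeR estimated for these libraries, DESeq2 made 110 false calls among 16433 unchanged genes and edgeR 3. Those 110 exceed the 44 real calls, so the simulated data do not match the real data in this respect. Such counts give no share of false calls among real calls, here or in the other comparisons. At a simulated 16-fold change edgeR recovered 50.8% of the changed genes that passed the filter and at 4-fold 4.62%.

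Gene groups fixed before the data were examined were tested as wholes. Cytosolic ribosomal protein genes were higher in Suv39h1wt than in Suv39h1mut embryos: 78 of 83 members had a positive fold change, with a median log2 fold change of 0.59. Rpl41 was at 412.7 ± 202.3 CPM against 185.8 ± 91.4, and Rpl29 at 34.8 ± 33.3 CPM against 8.32 ± 0.28. In camera with a preset correlation the list rose (adjusted p = 2.11e-07), but not with an estimated correlation (adjusted p = 0.710). The difference in list score was 0.76 between the libraries numbered 1 and 0.60 between those numbered 2, yet the median was -0.00 without Suv39h1wt replicate 2 and 0.16 without Suv39h1mut replicate 1, which ended the call (adjusted p of 0.350 and 0.675 in camera), and 1.38 without Suv39h1mut replicate 2 and 1.07 without Suv39h1wt replicate 1. Leaving out 1 library unbalances the library numbers, and the score was higher in number 2 than in number 1 by 0.88, 1.24 and 1.07 in non-injected, Suv39h1mut and Suv39h1wt embryos. With the replicate number as a block the median was 0.58 (camera adjusted p = 3.43e-11, and 0.525 with an estimated correlation), and 0.53 to 0.85 without 1 library, with the call kept each time at the preset correlation.

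The transient 2-cell programme, genes that share their activation with the MERVL retrotransposon and the transcription factor Dux, was also higher in Suv39h1wt embryos, with 31 of 42 members positive and a median log2 fold change of 0.42. Gm6763 was at 145.2 ± 16.8 CPM in Suv39h1wt against 51.2 ± 22.7 CPM in Suv39h1mut, and the pseudogene Gm2056 at 36.7 ± 19.2 CPM against 11.02 ± 5.92. The list rose in camera (adjusted p = 0.00993), but not with an estimated correlation (adjusted p = 0.615). Without Suv39h1mut replicate 2 the median was 0.24 (adjusted p = 0.123) and without Suv39h1wt replicate 1 it was 0.36 (adjusted p = 0.230), while without Suv39h1mut replicate 1 it was 0.77. With the block the call was lost without Suv39h1mut replicate 2 (median 0.27, camera adjusted p = 0.0561), Suv39h1wt replicate 1 (0.66, 0.106) or Suv39h1wt replicate 2 (0.28, 0.112). Many members of this list are copies that share sequence and reads, so the values of single copies are uncertain.

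Of the heat shock and integrated stress response genes, 27 of 40 were higher, with a median log2 fold change of 0.35. Ddit3, the stress-induced transcription factor CHOP, was at 7.95 ± 2.99 CPM against 1.34 ± 0.40, and Hmox1, heme oxygenase 1, at 10.0 ± 0.04 CPM against 2.84 ± 0.31. In non-injected embryos Ddit3 was at 5.24 ± 3.42 CPM and Hmox1 at 8.60 ± 1.47 CPM. Against non-injected embryos the list median was 0.17 for Suv39h1wt and -0.35 for Suv39h1mut (camera adjusted p = 0.724 and 0.168). For Suv39h1wt vs Suv39h1mut the list passed narrowly in camera (adjusted p = 0.0425, and adjusted p = 0.615 with an estimated correlation). The call was lost with the replicate number as a block (adjusted p = 0.0520), with upper-quartile scaling (adjusted p = 0.0513) and without any 1 of the 4 injected libraries (medians of 0.29 to 0.48, adjusted p from 0.0760 to 0.254). With the block the median was 0.29, and 0.11 without Suv39h1wt replicate 2 (camera adjusted p = 0.358) to 0.42 without Suv39h1wt replicate 1.

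Mitochondrially encoded genes were higher in 30 of 32 members, with a median log2 fold change of 0.52. The tRNA gene mt-Ts1 was at 35.4 ± 9.19 CPM against 12.96 ± 7.29, and mt-Te at 1.74 ± 1.03 against 0.40 ± 0.27. The list rose in camera (adjusted p = 0.00180, and adjusted p = 0.710 with an estimated correlation). The score differed by 0.05 between the libraries numbered 1 and by 0.99 between those numbered 2. Without Suv39h1wt replicate 2 the median was -0.16 (adjusted p = 0.876), and without Suv39h1wt replicate 1 it was 1.14. With the block the call was lost without Suv39h1mut replicate 2 (median 0.12, camera adjusted p = 0.468) or Suv39h1wt replicate 2 (0.16, 0.380).

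Olfactory and vomeronasal receptor genes, a large family known for its role in sensory neurons, were lower in Suv39h1wt than in Suv39h1mut embryos in 66 of 93 tested members, with a median log2 fold change of -1.08. It was -1.03 with the 17 members at 0 in a whole group set at their bound. Olfr60 had 0 counts in both Suv39h1wt libraries against 312 and 32, at least 45.0-fold lower, and Vmn1r53 had 0 against 62 and 19, at least 10.7-fold lower. These genes were near the floor, with a median over members of 0.487 CPM, and among the 32 members with a mean of at least 1 CPM the median was -0.56, with 22 lower and 10 higher. The list fell in camera (adjusted p = 0.000435, and adjusted p = 0.615 with an estimated correlation). Without Suv39h1mut replicate 1 the median was 0.00 (adjusted p = 0.471), without Suv39h1wt replicate 2 the call was lost (adjusted p = 0.350), and without Suv39h1wt replicate 1 the median was -3.49. The score was lower in number 2 than in number 1 by 0.42, 1.09 and 0.99 in non-injected, Suv39h1mut and Suv39h1wt embryos, and lower in Suv39h1wt than in Suv39h1mut by 0.95 between the libraries numbered 1 and 0.85 between those numbered 2. With the block the median was -1.26 (camera adjusted p = 0.000224, and 0.525 with an estimated correlation), and the call was lost without Suv39h1mut replicate 1 (-1.11) or Suv39h1wt replicate 1 (-1.09).

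The H3K9 methylation and heterochromatin machinery did not pass for Suv39h1wt vs Suv39h1mut. Of 41 members, 18 were higher and 23 lower, with a median log2 fold change of -0.10 (camera adjusted p = 0.966). The members with the smallest p were the H3K9 demethylase gene Kdm3b, at 45.9 ± 15.9 CPM in Suv39h1wt against 20.1 ± 4.78 CPM in Suv39h1mut, and the zinc-finger gene Zfp462, at 0.99 ± 0.67 against 4.99 ± 2.66. The median log2 fold change was 0.16 for ribosome biogenesis and nucleolus genes (adjusted p = 0.128), 0.05 for proteasome subunits (0.361), 0.20 for canonical histone genes (0.596), -0.01 for maternal oocyte transcripts (0.486), 0.17 for pluripotency and early lineage regulators (0.321) and 0.02 for cell cycle genes (0.400), all in camera. It was -0.01 for p53 and DNA damage response genes (0.301), 0.28 for interferon and foreign RNA response genes (0.210), 0.33 for imprinted genes (0.0601) and -0.09 for 336 Zfp-named zinc-finger genes (0.373). Among markers of other cells, it was 1.41 for 14 cumulus and granulosa genes (0.247), 0.01 for 8 sperm and spermatid genes (0.534) and -0.09 for 11 blood genes (0.966). For the H3K9, maternal, p53 and sperm lists the sign of the test, the median or the mean differed, with means of -0.06, 0.00, 0.24 and -0.78. In all 19 lists, 0 members passed for Suv39h1wt vs Suv39h1mut in edgeR, over all genes or adjusted over the list alone. Over the 57 tests of lists in the 3 comparisons, 15 passed in camera with the preset correlation, 0 with an estimated one and 0 in fry.

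**Figure D2:**
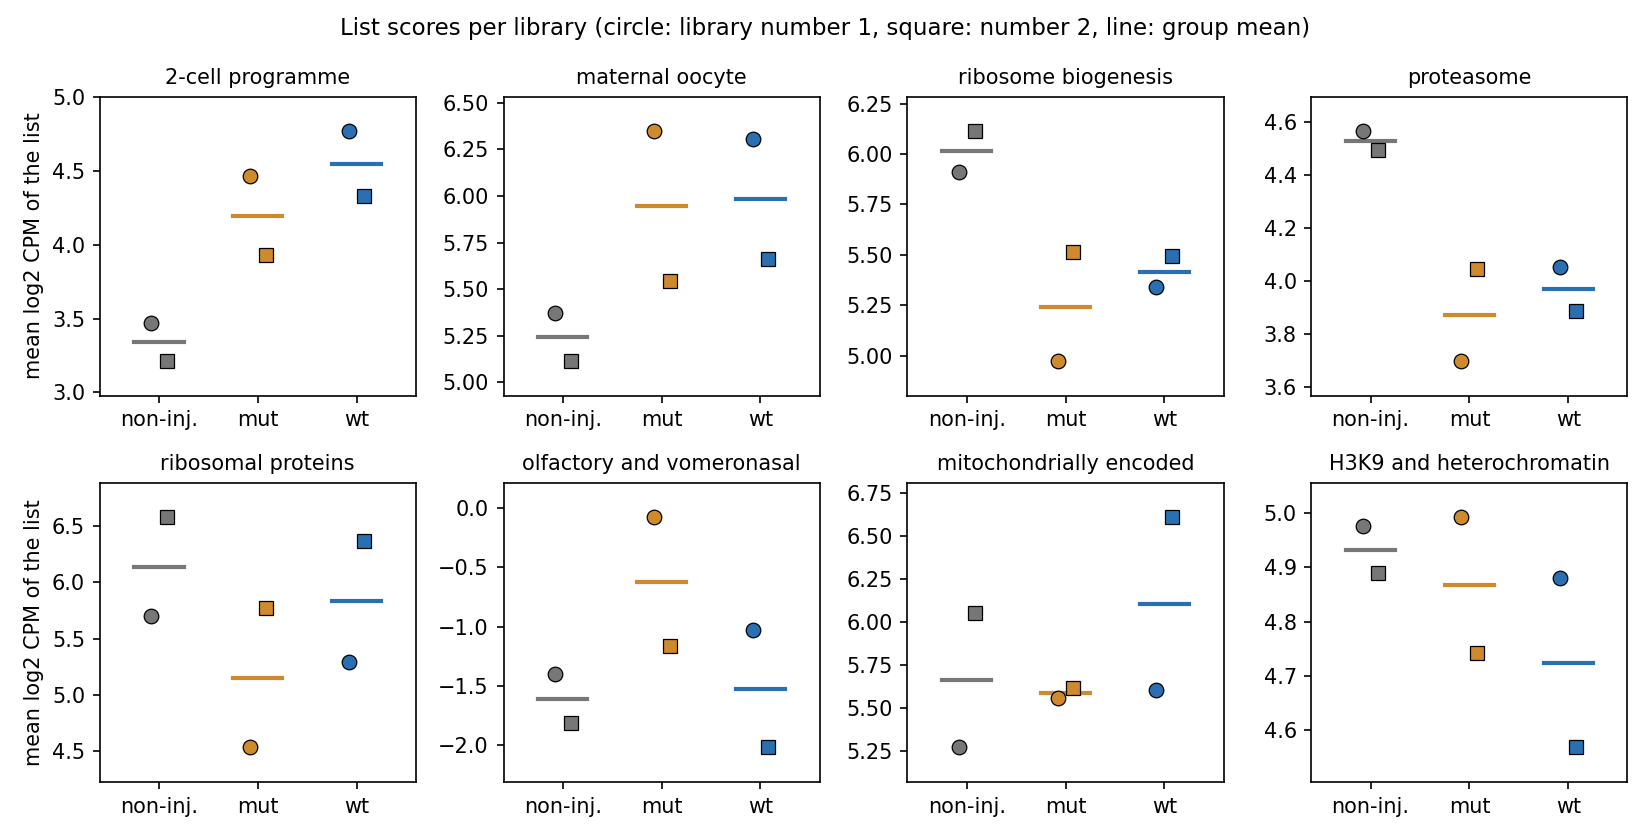
List scores (mean log2 CPM over the members of a list, vertical axes with their own ranges) in each library, by group. Circles are libraries numbered 1, squares libraries numbered 2 and lines group means; for the 2-cell programme both non-injected libraries (3.47 and 3.21) lie below the 4 injected ones (3.93 to 4.77), while ribosomal protein scores differ between numbers 1 and 2 in every group.

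Repeat elements were compared between Suv39h1wt and Suv39h1mut embryos. MERVL-int, the internal part of the retrotransposon that is transcribed at the 2-cell stage, gave 2494646 to 3575308 counts per library, at 122785 ± 29506 CPM of repeat counts in Suv39h1wt and 110987 ± 50228 CPM in Suv39h1mut embryos, a log2 fold change of 0.15 ± 0.47. Its long terminal repeat MT2_Mm was at 0.50 ± 0.45. Of the young LINE-1 families, L1Md_A was at -0.11 ± 0.23, L1Md_T at 0.37 ± 0.48 and L1Md_F2 at 0.00 ± 0.21. The major satellite GSAT_MM, a main site of H3K9me3, was at 0.40 ± 0.73, from 15498 to 96665 counts per library, and the minor satellite SYNREP_MM at 1.72 ± 0.92, from 157 to 2374 counts. MTA_Mm was at 0.53 ± 0.23, B1_Mm at 0.38 ± 0.30, B2_Mm2 at 0.28 ± 0.36 and IAPEz-int at 0.30 ± 0.25. Of these, MERVL-int, L1Md_A, L1Md_T, L1Md_F2, IAPEz-int, B1_Mm, B2_Mm2 and GSAT_MM changed sign under another scaling or without 1 library. Without 1 library MT2_Mm was at 0.06 to 1.09, SYNREP_MM at 0.89 to 3.88 and IAPEz-int at 0.05 to 0.57.

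The repeat families with the smallest p included endogenous retroviruses of the ERVK class. RLTR45 was at 2264 ± 74.9 CPM in Suv39h1wt against 991 ± 129 CPM in Suv39h1mut (log2 fold change 1.19 ± 0.20), and IAPLTR1_Mm at 539.0 ± 246.3 against 219.8 ± 91.7 (1.29 ± 0.39). RLTR9B2 was at 1.93 ± 0.64, and the simple repeats (T)n and (A)n at 0.64 ± 0.20 and 0.74 ± 0.25. Lower in Suv39h1wt were the DNA transposons Charlie25 (-2.17 ± 0.69) and Charlie6 (-1.70 ± 0.65), LTR73 (-2.44 ± 0.80), MLT1N2-int (-4.63 ± 1.71) and L1M3c (-1.40 ± 0.57). Without 1 library IAPLTR1_Mm was at 0.73 to 1.801, RLTR9B2 at 0.86 to 2.48, (A)n at 0.46 to 1.05 and LTR73 at -3.13 to -1.15. In edgeR, 0 of 1082 families passed (smallest adjusted p = 0.209), with 20 higher and 7 lower at an unadjusted p under 0.05, where chance gives 54.1. With the replicate number as a block, edgeR called 4 families (58 higher and 14 lower at an unadjusted p under 0.05), all 4 higher in Suv39h1wt: RLTR45 (adjusted p = 0.00116), IAPLTR1_Mm (0.0137), RLTRETN_Mm (0.0177) and (A)n (0.0294).

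By class, 94 of 146 ERVK families were higher in Suv39h1wt, with a median log2 fold change of 0.13 (camera adjusted p = 0.0555, 0.0322 with the block, and 0.674 with an estimated correlation). LINE L1 families were lower in 73 of 110, with a median of -0.09 (adjusted p = 0.241), and 18 of 21 SINE B1/Alu and 5 of 5 SINE B2 families were higher (0.311 and 0.430). ERVL and MERVL had a median of 0.03, ERVL-MaLR -0.03, ERV1 and other LTR -0.05, and DNA transposons -0.05, with adjusted p in camera from 0.311 to 0.954; for ERVL and MERVL the test had the opposite sign. Satellites had too few families for a test and made up 1.13% ± 0.34 of repeat counts in Suv39h1wt and 1.25% ± 0.09 in Suv39h1mut embryos (SD, n = 2). Structural RNA repeats made up 8.06% and 28.6% of repeat counts in Suv39h1wt replicates 1 and 2, and 6.92% and 24.7% in the Suv39h1mut replicates. The scaling moved the values of all families: the median of all families was 0.04 with TMM, -0.08 with upper-quartile scaling, -0.19 with scaling from the gene table and -0.33 with the authors' size factors. The share of families higher in Suv39h1wt was 53.7%, 43.0%, 34.3% and 24.7% in that order. Relative to that median, LINE L1 families were at -0.14 and MERVL-int at 0.08 to 0.19 under these scalings.

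**Figure D3:**
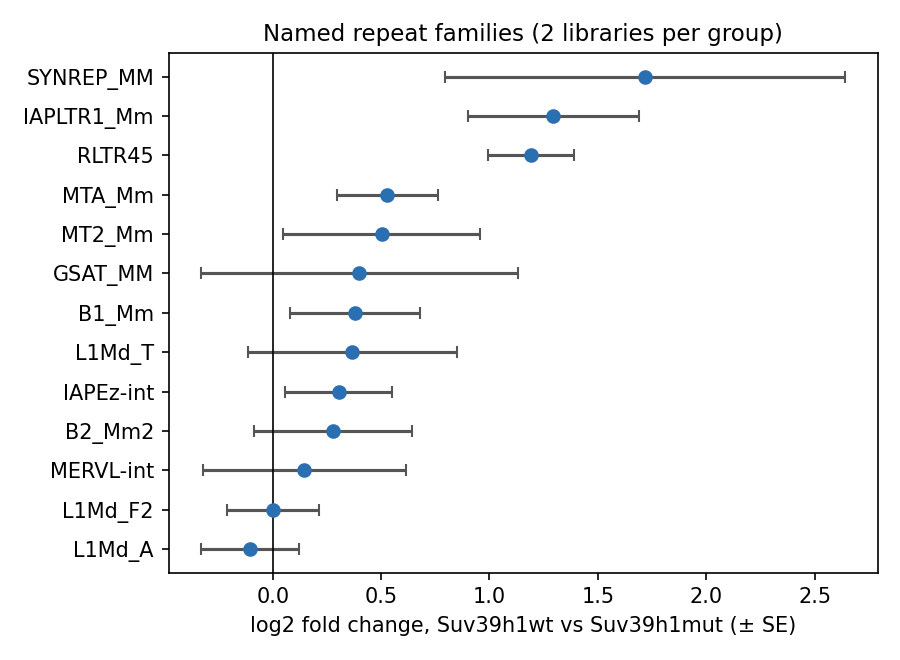
Log2 fold change of named repeat families in Suv39h1wt vs Suv39h1mut embryos (horizontal axis, TMM scaling within the repeat table). Points are estimates from 2 libraries per group and bars SE; RLTR45 (1.19 ± 0.20) has the smallest p, and MERVL-int, L1Md_A, L1Md_T, L1Md_F2, B2_Mm2 and GSAT_MM have bars that reach 0. The direction of MERVL-int, L1Md_T, L1Md_F2, B1_Mm, B2_Mm2 and IAPEz-int flips under the authors' size factors.

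The authors' deposited table of differentially expressed genes for this comparison lists 58 genes, 39 higher and 19 lower in Suv39h1wt. Of these, 55 were tested here, 55 in the direction of the authors' deposited table, 51 at an unadjusted p under 0.05 and 0 past adjusted p in edgeR, while 23 were among the 44 called by DESeq2. In the authors' deposited table Rbfa has a log2 fold change of 3.50 (adjusted p = 3.57e-05), Rffl -2.43 (0.000347), Igf2bp1 1.70 (0.0130) and Cdhr1 -3.01 (0.0124). The ubiquitin gene Ubb, at 1.28 (0.0474) in the authors' deposited table, had 8411 and 7009 counts in Suv39h1wt against 2659 and 4828, and Men1, the menin tumour suppressor, at -2.67 (0.0180) there, had 39 and 20 against 343 and 648. In 51 of the 58 genes of the authors' deposited table the Suv39h1wt and Suv39h1mut libraries did not overlap. In 37 the authors' normalized counts of 1 library of a group were over 5 times the other, as for Flad1, with 97 and 5846 raw counts in the Suv39h1mut libraries. None of the 58 genes belongs to a list fixed here. The authors' deposited table of repeat families lists 19, 3 higher and 16 lower, among them IAPLTR1_Mm at 0.81 (adjusted p = 0.0207), RLTR45 at 0.74 (0.0207) and L1M3c at -1.22 (0.0207). All 19 families of the authors' deposited table had the same direction here, and 7 had an unadjusted p under 0.05. The authors' gene and family lists come from the same libraries as the tests here, so a shared direction is no separate support. With the authors' size factors 24.7% of all families were higher in Suv39h1wt, with a median log2 fold change of -0.33.

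The comparison of Suv39h1wt with non-injected embryos does not separate injection from the mRNA injected. Of the 5 higher genes with the smallest p in edgeR, Gm6763 and Gm8300 belong to the 2-cell list, Gm2046 and BB287469 lie near Gm8300, and Akap5 is in neither group. Gm6763 (chromosome 10, 103606899 to 103616256) was at 145.2 ± 16.8 CPM in Suv39h1wt against 19.5 ± 6.08 CPM in non-injected embryos, a log2 fold change of 2.90 ± 0.54. On chromosome 12, Gm2046 (89211972 to 89218668) was at 3.86 ± 0.75, BB287469 (89055025 to 89059124) at 3.09 ± 0.70 and Gm8300 (88855266 to 88859203) at 2.44 ± 0.56. Akap5, an anchoring protein of protein kinase A, had 192 and 1008 counts against 9 and 7. Lower in Suv39h1wt were Rffl (-3.27 ± 0.74), the trichoplein gene Tchp (3.89 ± 0.52 CPM against 37.9 ± 16.8) and the transporter gene Mfsd5 (9.50 ± 1.58 CPM against 54.5 ± 1.47). Cdhr1 had 0 counts against 109 and 97, at least 38.9-fold lower. In edgeR 0 of 17638 genes passed for Suv39h1wt vs non-injected (smallest adjusted p = 0.753), with 528 higher and 558 lower at an unadjusted p under 0.05. With the replicate block 0 passed (smallest adjusted p = 0.108), with 962 higher and 841 lower. DESeq2 called 284 genes, 143 higher and 141 lower, of which 45 had a group at 0 and 6 belonged to the 2-cell list, with the smallest adjusted p among higher genes for Gm10154 (7.59e-11), Ak3 and Akap5 (both 1.81e-05). In simulated data for this comparison DESeq2 made 129 false calls among 16488 unchanged genes.

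Genes of the 2-cell programme were higher in Suv39h1wt than in non-injected embryos in 33 of 42 members, with a median log2 fold change of 1.11. The list rose in camera (adjusted p = 1.22e-07, and adjusted p = 0.615 with an estimated correlation), and 7 members passed in edgeR adjusted over the list alone against 0 over all genes. Maternal oocyte transcripts were higher in 79 of 89 members, with a median of 0.81. Nlrp9a, an oocyte gene of the NLR family, was at 196.6 ± 43.2 CPM against 54.0 ± 17.3, and Cnot7, a deadenylase subunit that acts in mRNA decay, at 426.0 ± 199.9 CPM against 136.3 ± 43.4. That list rose in camera (adjusted p = 6.10e-06, and adjusted p = 0.634 with an estimated correlation), with a median of 0.41 without Suv39h1wt replicate 1, or 0.89 with the block. Ribosome biogenesis and nucleolus genes were lower in 64 of 72 members, with a median of -0.56. Gnl3l, a nucleolar GTPase, was at 10.4 ± 1.48 CPM against 35.5 ± 4.22, and Ftsj3, a factor of ribosomal RNA processing, at 10.8 ± 4.15 against 33.4 ± 9.98. That list fell in camera (adjusted p = 0.000318, and adjusted p = 0.615 with an estimated correlation), and lost its call without Suv39h1wt replicate 1 (median -0.48, adjusted p = 0.0827), but not with the block (-0.62, 0.00789). Proteasome subunits were lower in 27 of 36, with a median of -0.42. Psmd11 was at 40.2 ± 3.48 CPM against 112.9 ± 59.0, and Psmb10, a subunit of the immunoproteasome, at 0.90 ± 0.76 against 12.4 ± 2.74. The proteasome list fell in camera (adjusted p = 0.0299, and adjusted p = 0.615 with an estimated correlation). It lost its call without non-injected replicate 1 (median -0.15, adjusted p = 0.192), non-injected replicate 2 (-0.40, 0.0660), Suv39h1mut replicate 1 (-0.41, 0.0550) or Suv39h1wt replicate 1 (-0.72, 0.141). With the block and without non-injected replicate 1, the medians were -0.32 for ribosome biogenesis (camera adjusted p = 0.0677) and -0.18 for the proteasome (0.441), and the proteasome call was also lost without Suv39h1mut replicate 1 (0.0643), Suv39h1wt replicate 1 (0.176) or Suv39h1wt replicate 2 (0.108).

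The other 15 lists did not pass in camera for Suv39h1wt vs non-injected. With the replicate block, cytosolic ribosomal proteins (median -0.28 without the block, adjusted p = 0.199) reached adjusted p = 0.0440 and mitochondrially encoded genes (median 0.45, adjusted p = 0.0756) reached 0.0250, but 0.619 and 0.715 with the block and an estimated correlation. Of the cumulus and granulosa markers, 12 of 14 were higher, with a median of 1.32 (adjusted p = 0.101). Vim, vimentin, had 227 and 65 counts in the Suv39h1wt libraries, 2 and 93 in the Suv39h1mut libraries and 0 in both non-injected libraries, and Sparc, an extracellular matrix protein, had 397 and 400, 121 and 104, and 19 and 28. Of the H3K9 list, 22 of 41 were lower (median -0.13, adjusted p = 0.584), with Ehmt1, an H3K9 methyltransferase, at 19.4 ± 4.30 CPM against 43.4 ± 21.8. Interferon and foreign RNA response genes had a median of 0.20 (adjusted p = 0.310), with the nucleic acid sensor Zbp1 at 38 and 126 counts against 1 and 0 and Parp14 at 294 and 302 against 61 and 24. Pluripotency and early lineage regulators had a median of -0.22 but a mean of 0.35 and a test of positive sign (adjusted p = 0.584). Tead4, a transcription factor of the trophectoderm lineage, was at 4.04 ± 1.15 CPM against 26.6 ± 7.32, and Sox17, a transcription factor of endoderm, had 126 and 21 counts against 0 in both, at least 18.1-fold higher. Olfactory and vomeronasal receptor genes had a median of 0.22 and a mean of -0.04 (adjusted p = 0.819).

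The comparison of Suv39h1mut with non-injected embryos does not separate injection from the mRNA injected either. Higher genes with the smallest p included Pppde1 (chromosome 1, 180117548 to 180182729), a peptidase-family gene at 351.2 ± 135.6 CPM in Suv39h1mut against 93.2 ± 22.0 CPM in non-injected embryos, a log2 fold change of 1.91 ± 0.49. The WD-repeat gene Wdr69 was at 12.04 ± 3.77 CPM against 0.68 ± 0.19. Rassf6, a Ras association domain gene, had 329 and 103 counts against 0, at least 50.4-fold higher, 4930481A15Rik 213 and 241 against 0, at least 54.5-fold higher, and C330018A13Rik 605 and 39 against 0, at least 73.7-fold higher. These bounds are ratios of group means and do not hold for each library, as the 605 and 39 counts show. Lower genes with the smallest p included Dhx34 (0.08 ± 0.08 CPM against 6.08 ± 4.78), Ccdc88b (0.13 ± 0.05 against 9.60 ± 8.20), AI462493 (1.03 ± 0.76 against 16.9 ± 1.54) and 9330160F10Rik (1.22 ± 0.55 against 32.0 ± 15.4). In edgeR 0 of 17638 genes passed for Suv39h1mut vs non-injected (smallest adjusted p = 0.880), with 412 higher and 369 lower at an unadjusted p under 0.05. With the replicate block 0 passed (smallest adjusted p = 0.185), with 909 higher and 852 lower. DESeq2 called 59 genes, 32 higher and 27 lower, of which 20 had a group at 0; in simulated data for this comparison it made 135 false calls among 16586 unchanged genes. Upper-quartile scaling moved the median of all genes in this comparison from 0.02 to 0.13.

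Cytosolic ribosomal protein genes were lower in Suv39h1mut than in non-injected embryos in 80 of 83 members, with a median log2 fold change of -0.95. Rpl27 was at 12.7 ± 7.89 CPM against 60.3 ± 38.5 and Rplp1 at 56.9 ± 45.8 CPM against 233.0 ± 96.7. The list fell in camera (adjusted p = 5.39e-10, and adjusted p = 0.670 with an estimated correlation). Its median was -0.45 without Suv39h1mut replicate 1 (adjusted p = 0.0550, past the threshold no longer), -0.39 without non-injected replicate 2 and -1.65 without Suv39h1mut replicate 2. With the block it was -0.93 without Suv39h1mut replicate 1 and -0.81 to -1.15 without any 1 library, with the call in camera kept each time at the preset correlation. With all libraries, the block and an estimated correlation the ribosomal protein list did not pass (camera adjusted p = 0.525). Ribosome biogenesis and nucleolus genes were lower in 62 of 72 members, with a median of -0.72 (camera adjusted p = 1.15e-07, and adjusted p = 0.615 with an estimated correlation). Rrp15 was at 6.21 ± 0.83 CPM against 35.9 ± 29.0 and Mrto4 at 22.2 ± 0.57 against 68.8 ± 14.1. Proteasome subunits were lower in 27 of 36, with a median of -0.78 (camera adjusted p = 0.000318, and adjusted p = 0.615 with an estimated correlation). Psmc3, an ATPase of the proteasome, was at 8.28 ± 0.23 CPM against 40.5 ± 7.64, and Psmd4 at 11.5 ± 1.68 against 45.4 ± 7.80. The proteasome median was -0.48 without Suv39h1mut replicate 1 (adjusted p = 0.0550), -0.47 without non-injected replicate 1 and -0.46 without non-injected replicate 2. With the block the proteasome call was lost without Suv39h1mut replicate 1 (-0.33, camera adjusted p = 0.0900) or non-injected replicate 1 (-0.47, 0.0694).

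The 2-cell programme was higher in Suv39h1mut than in non-injected embryos in 35 of 42 members, with a median of 0.93 (camera adjusted p = 0.000318, and adjusted p = 0.615 with an estimated correlation). Gm8300 was at 97.3 ± 19.7 CPM against 32.99 ± 7.51 and Gm6763 at 51.2 ± 22.7 against 19.5 ± 6.08. Without Suv39h1mut replicate 1 the median was 0.49 (adjusted p = 0.0550). Maternal oocyte transcripts were higher in 74 of 89 members, with a median of 0.73 (camera adjusted p = 0.000164, and adjusted p = 0.670 with an estimated correlation). Nlrp9a was at 209.8 ± 127.5 CPM against 54.0 ± 17.3 and Khdc1c at 286.7 ± 88.1 against 102.3 ± 36.6. Without Suv39h1mut replicate 1 the maternal median was 0.23 (adjusted p = 0.269). With the block and without that library, the medians were 0.68 for the 2-cell list (camera adjusted p = 0.0230) and 0.57 for the maternal list (0.0195), and both lists kept their call without any 1 library. Olfactory and vomeronasal receptor genes were higher in 70 of 93 members, with a median of 1.05, or 1.00 with the 15 members at 0 in a whole group set at their bound (camera adjusted p = 0.000318, and adjusted p = 0.615 with an estimated correlation). Olfr787 had 313 and 410 counts against 20 and 13, and the pseudogene Olfr759-ps1 58 and 28 against 0, at least 10.1-fold higher. The receptor median was 0.00 without Suv39h1mut replicate 1 (adjusted p = 0.438), 1.58 without non-injected replicate 2 (adjusted p = 0.518) and 2.30 without non-injected replicate 1. With the block the call was lost without Suv39h1mut replicate 1 (0.62, camera adjusted p = 0.129), non-injected replicate 1 (0.95, 0.206) or non-injected replicate 2 (1.70, 0.0815). Among the 32 members with a mean of at least 1 CPM the median was 1.09, with 29 higher.

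The other 13 lists did not pass in camera for Suv39h1mut vs non-injected, and 0 members of any list passed in edgeR, over all genes or adjusted over the list alone. Of the H3K9 list, 23 of 41 members were lower (median -0.21, adjusted p = 0.534), with the H3K9 methyltransferase gene Ehmt2 at 3.41 ± 0.71 CPM against 20.7 ± 16.8 and the H4K20 methyltransferase gene Suv420h1 at 30.1 ± 2.72 against 67.9 ± 11.6. Interferon and foreign RNA response genes had a median of -0.01 and a mean of 0.29 (adjusted p = 0.966), with Irf3 at 1.14 ± 0.28 CPM against 11.5 ± 2.00. Of the cumulus and granulosa markers, 8 of 14 were higher, with a median of 0.32 and a mean of 1.35 (adjusted p = 0.442). Heat shock and stress genes had a median of -0.35 (adjusted p = 0.168) and p53 and DNA damage genes one of -0.33 (adjusted p = 0.275). For the pluripotency, sperm and blood lists the mean (0.24, 0.32 and 0.10) and the median (-0.12, -0.63 and -0.27) had opposite signs.

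The comparisons of both injected groups with the same non-injected libraries were set side by side. Across the 17638 genes their log2 fold changes had a correlation of 0.607, against 0.505 on average (0.482 to 0.522) in 20 simulated data sets with unchanged groups and the same controls; genes are not independent replicates. The covariance was 2.51 against a simulated 1.23. A covariance also grows with the spread of the fold changes, which was smaller in the simulated sets. Its excess alone therefore does not show a shared change. These data sets carry no pairing by library number; in 20 others that kept the estimated difference between numbers, the correlation was 0.479 to 0.518. With the replicate block the observed correlation was 0.603, against 0.478 to 0.520 in such sets. Leaving out 1 library gave 0.416 (without Suv39h1wt replicate 1) to 0.677 (without non-injected replicate 1), and also changes the value without any effect. Against simulated sets without pairing that lacked the same library, the correlation was higher without any 1 of the 4 injected libraries (0.416 against 0.353 to 0.393 for Suv39h1wt replicate 1). It was lower without non-injected replicate 1 (0.677 against 0.713 to 0.737) or replicate 2 (0.641 against 0.711 to 0.733). The covariance was above the simulated ones in all 6, with the same limit of a smaller simulated spread. At an unadjusted p under 0.05 in both, 193 genes were higher in both and 113 lower in both, against simulated means of 160.5 and 35.2 and, for independent lists, 12.3 and 11.7. The 2 non-injected libraries could not be split into separate control sets of 2.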

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

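The checks of gene length and GC content were set for list differences already seen, before the outcome of these checks was seen. The tests of single libraries, with the replicate block, were chosen after the results were seen. For Suv39h1wt vs Suv39h1mut, 5 gene lists differed between these groups by camera's test with the preset correlation. Their median log2 fold changes were 0.42 for the 2-cell programme, 0.59 for cytosolic ribosomal proteins, 0.35 for heat shock and stress genes, -1.08 for olfactory and vomeronasal receptors and 0.52 for mitochondrially encoded genes. None of the 5 passed with an estimated correlation.

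Higher ribosomal protein genes in Suv39h1wt than in Suv39h1mut embryos could reflect gene length and GC content, since these genes are short. After the length and GC trend was subtracted in the fit with the replicate block, the median was 0.46 against 0.58 before, which speaks against that explanation. For a single library as the reason, the score was higher in Suv39h1wt in 2 of 2 same-numbered pairs (by 0.76 and 0.60). With the block the median was 0.53 to 0.85 without any 1 library, with the call kept each time. With all libraries, the block and an estimated correlation the list did not pass (camera adjusted p = 0.525). A block fit without 1 library rests mainly on the pair that remains, so it adds little to the pair differences. These values speak against a single library only if the numbers mark true pairs, which the labels do not say. Unpaired, the scores overlap, with 5.30 in Suv39h1wt replicate 1 below 5.77 in Suv39h1mut replicate 2. The median of -0.00 without Suv39h1wt replicate 2 came from the fit without the block, where leaving out a library unbalances the library numbers, and the score differed between numbers in every group. Against non-injected embryos the list median was -0.28 for Suv39h1wt (camera adjusted p = 0.199) and -0.95 for Suv39h1mut (5.39e-10). The larger departure was thus in Suv39h1mut, though neither passed with an estimated correlation (camera adjusted p of 0.944 and 0.670). An effect of the wild-type or the mutant protein on these genes was not tested further.

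Lower olfactory and vomeronasal receptor genes in Suv39h1wt than in Suv39h1mut embryos could rest on 1 library or not, which these values leave open. The score was lower in both same-numbered pairs, by 0.95 and 0.85, and with the replicate block the median was -1.26 (camera adjusted p = 0.000224, and 0.525 with an estimated correlation). In that fit the median was -1.11 without Suv39h1mut replicate 1, but the list no longer passed (adjusted p = 0.0944), and these genes lie near the floor. The median of 0 without that library in the fit without the block does not decide, since libraries numbered 1 had the higher score in every group. The low-count filter was also applied anew without a library, with or without the block. With 1 library left in a group it needs the minimum count in only 1 library, so more members near the floor can enter. Suv39h1mut replicate 1 also had the most genes with a count, 22349. Genomic DNA carried into libraries would be 1 possible reason and de-repression of silent genes another; neither was tested. Subtraction of the length and GC trend had not been set beforehand for this list. Among its 75 members with such values, it moved the block median from -1.27 to -1.06 for Suv39h1wt vs Suv39h1mut. For Suv39h1mut vs non-injected the block median moved from 1.05 to 0.55.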

How the results depend on the processing

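Of 1336 values for named genes and repeat families under the alternatives, 1237 kept their direction and side of the threshold, 74 came to pass and 25 reversed. Of 270 values for lists that passed, 193 were kept, 75 no longer passed and 2 reversed. Except where stated, the cause was not tested. The comparisons of repeat families with non-injected embryos were not run, and for repeats the fit of only the 4 libraries compared is the main fit.

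Genes passing numbered 0 in each comparison of the main fit. In the order Suv39h1wt vs Suv39h1mut, Suv39h1wt vs non-injected and Suv39h1mut vs non-injected, they numbered 44, 284 and 59 with DESeq2, 20, 177 and 18 with DESeq2 and a fold-change prior, and 18, 33 and 9 with no filter. Leaving out 1 library gave 0 to 18, 0 to 44 and 0 to 1. Repeat families passing numbered 0, but 1 with DESeq2, 4 with the replicate block, 1 with scaling from the gene table and 1 with the authors' size factors. Repeat classes passing numbered 0, but 1 with the block, and 0 to 3 without 1 library. List tests passing numbered 15, but 0 with an estimated correlation, 0 with the replicate block and an estimated correlation, 7 to 18 without 1 library, and 10 to 15 with the block and without 1 library. With all 6 libraries, the block changed no other call of a gene, repeat family, list or repeat class than those given in the report; among annotation terms 14 passed against 11. Of the authors' deposited table, 55 genes had the same direction, but 24 with at least 10 counts in every library, where fewer genes were tested. Without 1 library, where the filter was applied anew, they numbered 54 to 58. The Suv39h1 log2 fold change for Suv39h1mut vs non-injected was -0.44 to 0.13 without 1 library. The list medians for Suv39h1wt vs Suv39h1mut were -0.00075 to 1.38 for ribosomal proteins and -0.16 to 1.14 for mitochondrially encoded genes without 1 library.

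Reversed repeat families in Suv39h1wt vs Suv39h1mut were, with the authors' size factors, MERVL-int (-0.19), L1Md_T (-0.058), L1Md_F2 (-0.37), IAPEz-int (-0.076), B1_Mm (-0.012) and B2_Mm2 (-0.0439), and, with scaling from the gene table, MERVL-int (-0.0061) and L1Md_F2 (-0.23). L1Md_F2, at 0.00 in the main fit, was at -0.019 with DESeq2 size factors and with DESeq2, -0.12 with upper-quartile scaling, -0.00352 with no filter and -0.014 with at least 10 counts in every library. Both scalings also moved the median of all families, to -0.33 and -0.19. Without 1 library, ranges were -0.28 to 0.70 for MERVL-int, -0.33 to 0.065 for L1Md_A, -0.48 to 0.92 for L1Md_T, -0.054 to 0.027 for L1Md_F2, -0.019 to 0.72 for B1_Mm, -0.13 to 0.81 for B2_Mm2 and -0.90 to 1.06 for GSAT_MM. The effect of depth on genes near the floor was not tested.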

Other observations

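The chromosome 12 window, the annotation terms and the comparison of library numbers were chosen after the results were seen. So was the test of single non-injected libraries with the replicate block. The checks of length, GC content and shared reads were set for list differences already seen, before the outcome of these checks was seen. Predicted genes in a cluster on chromosome 12 (mm9, 88855266 to 89265882) were higher in Suv39h1wt than in non-injected embryos in 11 of 11 tested genes, among them Gm8300, Gm2016, Gm2046, BB287469 and the oocyte gene Oog1, with a median log2 fold change of 2.44 (0.78 to 3.86). The window was set by the outer ends of Gm8300, BB287469, Gm2046 and Gm2056. Of these, Gm8300, BB287469 and Gm2046 had been picked for their small p in this same comparison. Gm2056 had been picked in that way for Suv39h1wt vs Suv39h1mut, and Gm8300 also for Suv39h1mut vs non-injected. These genes are counted in the 11, so the 11 genes are not separate observations in any of the 3 comparisons. For Suv39h1mut vs non-injected, 10 of 11 were higher, with a median of 1.49, and for Suv39h1wt vs Suv39h1mut 11 of 11, with a median of 1.40, among them Oog1 at 0.02 ± 0.68. At an unadjusted p under 0.05 in edgeR, 9, 3 and 2 of the 11 were higher in these comparisons, in that order. Counts were highest in Suv39h1wt replicate 1 (Gm4027, 7534 against 556 in replicate 2). Without that library the median was 1.60 for Suv39h1wt vs non-injected and 0.35 for Suv39h1wt vs Suv39h1mut (9 of 11 higher), or 1.94 and 0.87 with the replicate block. With the block and without Suv39h1mut replicate 1 it was 0.74 for Suv39h1wt vs Suv39h1mut, against 1.25 with all libraries. For Suv39h1mut vs non-injected it was 0.81 without Suv39h1mut replicate 1, 0.95 without non-injected replicate 2 and 2.29 without non-injected replicate 1, and 1.31 to 1.62 with the block and without 1 library. Of these, 5 had words to count in the transcripts used, and 44.0% (Gm8300) to 98.5% (BB287469) of their words of 31 bases occur in other genes, with 89.1% for Gm2016.

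Genes of DNA-directed RNA polymerases were lower in Suv39h1mut than in non-injected embryos in 30 of 31, with a median log2 fold change of -0.84 (camera adjusted p = 0.00226 over 2964 tests of 988 annotation terms, and 1.00 with an estimated correlation). For Suv39h1wt vs non-injected, 24 of 31 were lower, with a median of -0.70 (adjusted p = 0.283). Polr3e, a subunit of RNA polymerase III, was at -1.98 ± 0.62 for Suv39h1mut vs non-injected, and Polr2e was at -1.99 ± 0.50 for Suv39h1wt vs non-injected. With the preset correlation 11 term tests passed in all, and 0 with an estimated one. With the replicate block 14 passed; the 3 added were higher in Suv39h1wt than in Suv39h1mut embryos: translation (adjusted p in camera from 0.0599 to 0.00199), and the cytosolic small (0.0599 to 0.00128) and large (0.123 to 0.0110) ribosomal subunits. Terms for rRNA processing (-0.68, adjusted p = 8.07e-05) and structural constituents of the ribosome (-0.93, adjusted p = 1.18e-07) fell in Suv39h1mut vs non-injected by the same test.

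Many genes differed between library numbers in the same direction in every group. Of 2278 genes above 50 CPM, 497 were higher in number 2 in all 3 groups and 935 in number 1, or 62.9% with 1 direction where chance gives 25% for independent genes. Genes are not independent, so this does not show that the numbers mark true pairs. In each group the library numbered 2 had a larger share of counts in mt-Rnr1 and mt-Rnr2 (46.8%, 37.4% and 47.3% against 37.0%, 28.7% and 26.7% in non-injected, Suv39h1mut and Suv39h1wt embryos). It also had fewer genes with a count. The small RNA genes mmu-mir-689-2 and 7SK were higher in number 2 in all 3 groups.

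In both injected groups the 2-cell and maternal lists were higher, and the ribosome biogenesis and proteasome lists lower, than in non-injected embryos. Gene length and GC content are an unlikely reason, since 8 of 8 medians kept their sign and most of their size after that trend was subtracted. A single non-injected library is also an unlikely reason for the 2-cell and maternal lists, as 4 of 4 medians kept their sign, most of their size and their call in camera without either of them, in the fit with the replicate block; at an estimated correlation these lists did not pass with all libraries (adjusted p of 0.525 and 0.534). For the ribosome biogenesis and proteasome lists it stays open, since only 1 of 4 did so, ribosome biogenesis for Suv39h1mut vs non-injected. In that fit 3 of the 4 medians kept their sign and most of their size, and 2 of these lost their call. Both non-injected libraries had higher scores than all 4 injected ones for the proteasome (4.57 and 4.49 against 3.70 to 4.05) and ribosome biogenesis (5.91 and 6.11 against 4.97 to 5.51), which speaks against 1 library without deciding it. Cumulus and granulosa markers also had higher scores in all 4 injected libraries (-0.12 to 0.96) than in both non-injected ones (-0.44 and -0.63), but that list did not pass in camera (adjusted p of 0.101 for Suv39h1wt and 0.442 for Suv39h1mut vs non-injected). Reads shared between copies could contribute to the 2-cell result: among 8 members that share little sequence the lower of both medians was 0.40, for Suv39h1mut vs non-injected, against 0.93 for the whole list (5 of 8 higher). For Suv39h1wt vs non-injected it was 1.03 against 1.11 (6 of 8 higher), so the 2 comparisons differ and 8 members are too few to decide. A delay or other effect of injection itself on the turnover of maternal transcripts may give such a pattern in both groups; with no mock-injected group, this was not tested.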
